A study of Mus musculus with 18 samples.

How the data were processed

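INSERT-seq was applied to mouse embryonic stem cells of a CAST/129 hybrid background, with 3 biological replicates each of siNT, siWDR82 and siZC3H4. Per the labels' protocols, the insert locus was amplified from genomic DNA in successive rounds of PCR. RNA received spike-in RNA, was treated with DNase, reverse transcribed from a primer in mKate2 and amplified by PCR. No molecular identifiers are mentioned, so read numbers include PCR duplicates. Per the submitters' processing notes, cutadapt 1.14, Bowtie2 2.3.4.3, STAR and SAMtools were used with build mm10; which tool made which table is not given in the sources used here. The authors deposited raw read counts per reference sequence, one table for RNA and one for gDNA, with no normalization. The tables list 16461 inserts, 2556 spliced forms of 2404 of these inserts, and 5 spike-ins. The row for unassigned reads holds 0 reads. The column of sequence names has no header name, so columns were matched to samples by the names given for the 9 libraries of each table.

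The RNA of an insert was the sum of its unspliced and spliced reads, a choice made when the tests were written. Inserts with a mean of at least 20 gDNA and 5 RNA reads over the 9 libraries of each kind were tested, 15364 in all, which left out 1097. The main test was edgeR 4.0.16 (R 4.3.3) quasi-likelihood on the counts with 6 group means, and the contrast was RNA over gDNA in a knockdown minus RNA over gDNA in siNT. TMM factors were computed within RNA and within gDNA. The Benjamini-Hochberg threshold was 0.05. Levels per culture were log2 of CPM plus 0.5 for RNA minus the same for gDNA, scaled to library totals. Classes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1). Quantities per culture were compared with exact two-sided permutation tests, whose smallest p is 0.1 for 3 against 3 and 0.0238 for 6 against 3 cultures. Spliced against unspliced reads were tested in inserts with a mean of at least 20 of each.

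For the change by siNT level, inserts were ranked in 5 equal groups by one siNT culture and changes were taken against the others, in turn, so that noise in the ranking culture does not enter the change. Class differences at matched level used 20 such groups. A fold against a group at 0 reads is a lower bound against 3 reads over the group, and 1 to 3 reads were given an exact 95% Poisson interval. The chance correlation of the knockdown changes came from 100 simulations with no effect and one siNT group for both, and the chance overlap of calls from 20 such simulations with the model refitted. To predict what exchanged reads or carried-over DNA would do, an equal amount per insert, or the gDNA of the culture, was added to the siNT RNA libraries by calculation.

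Named inserts were chosen by a rule fixed before the data were examined, as the 10 largest rises and falls among inserts past the threshold whose knockdown cultures all lay on one side of the siNT cultures. The rule also named, per class and siRNA, the insert with the lowest p. As the inserts have no source gene here, 2 that rose and 2 that fell are printed, from the top of those lists. The insert of lowest p without a spliced form listed is printed too. The insert class was planned as origin or kind of sequence; the listing of a spliced form, the one class the names give, was used. Tests of sequence features, matched variants and gene lists were planned and not analysed here. Gene positions are from the RefSeq table for GRCm38, the assembly of mm10.

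RNA and gDNA libraries of the same siRNA and number deviated together from their group means in 9 of 9 cultures (r across inserts 0.29 to 0.47), so they were taken as pairs. The main model does not use this pairing. The fit with culture as a block, which does, is printed beside the counts. Replicates were not duplicates of one library, with a chi-square per degree of freedom of at least 32.3 in each pair. One spike-in had almost no reads, and the totals of all were used.

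Scripts were tested on simulated counts. For siWDR82 against siNT over 15364 inserts, the main model recovered 0% of 67 2-fold, 19.4% of 67 4-fold and 50% of 66 8-fold changes, with 3 false calls. With the culture as a block the shares were 0%, 10.4% and 43.9%, with 0 false calls. The simulated RNA and gDNA counts were drawn without a culture effect, so these shares do not rank the 2 models for paired libraries. A class shift of -0.5 was recovered as -0.53 in the median. The spliced-form test recovered 0% of 200 4-fold changes over 1527 inserts. Alternatives covered normalization, DESeq2 1.42.0, limma on log ratios, use of gDNA, filters, blocks, spike-in scaling, the libraries fitted and each replicate left out.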

Results

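The series measured how an inserted sequence sets the RNA made from one fixed place in the genome, and how that changed when a subunit of the Restrictor complex was depleted. Restrictor, whose core subunits are WDR82 and ZC3H4, attenuates early transcription by RNA polymerase II, above all of noncoding RNAs. In INSERT-seq, a pool of DNA inserts is integrated into the region of the upstream antisense RNA of Oct4 in mouse embryonic stem cells, ahead of an mKate2 reporter. Oct4 is the protein of Pou5f1, a pluripotency gene on mm10 chromosome 17 from 35506032 to 35510777. RNA reads of an insert were set against its genomic DNA (gDNA) reads, which give its representation in the cell pool. Cells received a non-targeting siRNA (siNT), siWDR82 or siZC3H4, with 3 biological replicates each and an RNA and a gDNA library per culture, 18 libraries in all. The siRNA dose was 30 nM, except that the labels of siWDR82 replicates 2 and 3 give 31 and 32 nM while the protocol gives 30 nM for all. Wdr82 (chromosome 9, 106170925 to 106191706) and Zc3h4 (chromosome 7, 16399583 to 16437696) are outside the amplified locus, so the depletion itself was not analysed here.

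RNA libraries held 32714145 to 53504904 reads and gDNA libraries 4584881 to 11510602. Of 16461 inserts, 15364 passed the count minimums, with a median of 216 to 558 gDNA reads per library. Inserts carry only a number, and the tables do not pair them with a sequence or a source gene. The one class the tables give is whether a spliced form of the insert is listed, which held for 2242 tested inserts against 13122 others.

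In siNT cultures, the steady-state RNA of inserts differed widely with the inserted sequence. The level, log2 of RNA over gDNA with each in CPM (reads scaled to the library total), ran from -4.06 at the 5th percentile to 1.69 at the 95th, a 53.7-fold range (26.4-fold with 2 CPM added to each value). The median SD of an insert between the 3 siNT cultures was 0.73. RNA over gDNA was above the library average for 1896 inserts and below it for 4038 (edgeR quasi-likelihood test, adjusted p under 0.05). Inserts with a spliced form listed had a median level of 0.0085 against -1.07 for the others, a difference of 1.08. That order rested on the spliced reads, since with unspliced reads alone the difference was -0.19.

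With either Restrictor siRNA, inserts with little RNA in siNT gained RNA relative to inserts with much. With siWDR82, the lowest of 5 equal bins of inserts by siNT level rose by a median log2 of 1.04 ± 0.075 (SD, n = 3), and the next bins by 0.80 ± 0.038, 0.46 ± 0.020 and 0.14 ± 0.026. The highest bin fell by 0.33 ± 0.057 on the scale of library totals, but stood at 0.62 ± 0.50 when RNA was scaled to spike-in reads. With siZC3H4 the values from the lowest to the highest bin were 0.87 ± 0.030, 0.69 ± 0.042, 0.47 ± 0.030, 0.22 ± 0.056 and -0.20 ± 0.034, the last of which was 0.34 ± 0.86 with spike-in scaling. Inserts were ranked in one siNT culture and the change was taken against the others. siNT cultures compared with each other in this way had an SD of 0.24 in the lowest bin and 0.095 in the highest. The lowest bin exceeded the highest by 1.38 ± 0.095 with siWDR82 and 1.07 ± 0.0074 with siZC3H4, in 6 of 6 knockdown cultures, against an SD of 0.32 for siNT. A two-sided permutation test of the 6 knockdown against the 3 siNT cultures gave p = 0.0238, the smallest this design allows, and 0.0357 after adjustment over 21 quantities. For either siRNA alone p was 0.1, the smallest that 3 against 3 cultures can give. For bin values these p-values are not exact. A siNT culture was set against fewer siNT cultures than a knockdown culture was, and nothing was recomputed when labels were permuted. The siNT mean of each bin value is 0 by construction.

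**Figure D1:**
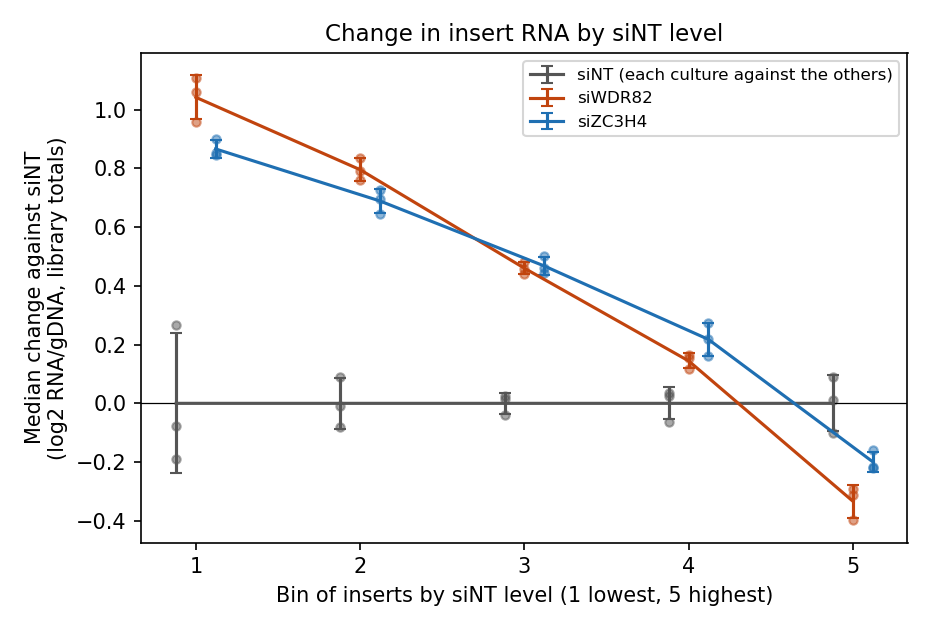
Median change in log2 RNA over gDNA against siNT (vertical axis, scaled to library totals) for 5 equal bins of the tested inserts ordered by siNT level (horizontal axis), with a point per culture, and lines and bars for the mean and SD of 3 cultures. Both knockdowns run from above 0.8 in the lowest bin to below 0 in the highest. The mean of siNT cultures compared with each other is 0 by construction, so only their spread is informative. With spike-in scaling, not plotted, the highest bin had a mean of 0.62 ± 0.50 with siWDR82 and 0.34 ± 0.86 with siZC3H4.

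The spread of RNA levels over inserts was narrower in both knockdowns. The interquartile range of log2 RNA over gDNA was 2.54 ± 0.23 in siNT, 1.77 ± 0.076 with siWDR82 and 1.98 ± 0.067 with siZC3H4 (n = 3 each; exact permutation p = 0.0238 for 6 against 3 cultures, 0.0357 adjusted). Tested inserts without any RNA read numbered 971 ± 146 per siNT culture, 396 ± 5.57 with siWDR82 and 407 ± 66.3 with siZC3H4. Insert reads per spike-in read, a measure of the total RNA of all inserts, were 26.0, 39.7 and 37.6 in siNT, 97.7, 46.3 and 61.8 with siWDR82, and 25.4, 59.5 and 79.5 with siZC3H4. The geometric mean was 1.93-fold higher with siWDR82 (exact permutation p = 0.1, n = 3) and 1.46-fold higher with siZC3H4 (exact permutation p = 0.4, n = 3). All 3 siWDR82 cultures lay above all 3 siNT cultures, but 0.1 is the smallest p that 3 against 3 can give. The 6 knockdown against the 3 siNT cultures gave an exact permutation p of 0.119, so a rise of total insert RNA is not shown. All changes of single inserts and classes are relative to the other inserts. Scaling to spike-in reads instead shifted the median log2 change of all inserts from 0.062 to 1.34 with siWDR82 and from 0.061 to 1.03 with siZC3H4.

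For single inserts, siWDR82 raised RNA over gDNA of 90 and lowered it for 17 of the 15364 tested (edgeR quasi-likelihood interaction test, adjusted p under 0.05). With RNA and gDNA of a culture paired as a block, 222 rose and 258 fell. Calls in both models numbered 81 up and 17 down. Spike-in scaling gave 611 up and 3 down, and limma on log ratios called 0. Of the 90 that rose, 49 had at most 3 RNA reads over the 3 siNT cultures together, a state shared by 422 tested inserts. Such inserts met the RNA minimum, a mean of 5 over the 9 libraries, only through their knockdown reads. Their rise was therefore set in part by that filter. Without those inserts 22 rose and 5 fell. With no count minimum 91 rose and 16 fell. Calls also moved with single cultures, to 26, 30 and 20 without siWDR82 replicates 1, 2 and 3 and to 211, 198 and 251 without siNT replicates 1, 2 and 3. On simulated counts for this comparison the test recovered 0% of 2-fold, 19.4% of 4-fold and 50% of 8-fold changes, so most 2-fold and 4-fold changes went uncalled in the simulation.

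siZC3H4 raised RNA over gDNA of 50 inserts and lowered it for 4 (edgeR, same model), and 50 rose and 11 fell with the culture as a block. Calls in both models numbered 34 up and 3 down. Library totals gave 88 up and 2 down, spike-in scaling 88 up and 1 down, and limma 0 up and 2 down. Of the 50 that rose, 32 had at most 3 siNT RNA reads in all, and without such inserts 8 rose and 2 fell. These too met the RNA minimum only through knockdown reads. With no count minimum 49 rose and 3 fell. Leaving out siZC3H4 replicates 1, 2 and 3 gave 13, 12 and 22 calls, and leaving out siNT replicates 1, 2 and 3 gave 246, 129 and 183.

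The inserts that rose most were nearly silent in siNT, and entered the tests only through their knockdown RNA reads. sequence_09565 had 0 RNA and 527 gDNA reads over the siNT cultures, but 679 RNA and 308 gDNA reads with siWDR82 and 412 and 174 with siZC3H4. Its RNA over gDNA was at least 218-fold higher with siWDR82 (edgeR adjusted p = 0.011) and at least 328-fold higher with siZC3H4 (edgeR adjusted p = 0.0116, but 0.0518 with the culture as a block), against a floor of 3 reads over the group. The siZC3H4 call was lost when any one siZC3H4 replicate was left out (adjusted p = 0.0502 to 0.0866). sequence_09907 had 1 RNA read and 1992 gDNA reads in siNT. Its pooled ratio was 3253-fold higher with siWDR82 (95% Poisson interval 584 to 128500, edgeR adjusted p = 0.00083) and 1627-fold higher with siZC3H4 (292 to 64250, adjusted p = 0.00166). Intervals and floors cover counting error only, since PCR reads are not independent molecules. None of the 10 inserts with the largest rise had a spliced form listed, with either siRNA. Such forms were rare at this level, since only 11 of the 206 tested inserts with 0 siNT RNA reads had one. Among inserts without a form listed, sequence_11860 had the lowest p with either siRNA, at 1 RNA read in each siNT culture. Its log2 change was 8.38 with siWDR82 (edgeR adjusted p = 0.000136, or 0.00319 with the culture as a block). With siZC3H4 it was 8.03 (edgeR adjusted p = 0.000298, or 0.00701 with the block).

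Fewer inserts fell than rose with either siRNA in the model without the block. sequence_15181, of which 91.5% of RNA reads were spliced, went from a level of 2.73 ± 0.45 in siNT to -0.32 ± 1.07 with siWDR82 (n = 3; log2 change -3.68, SE 0.75, edgeR adjusted p = 0.0223). The call was lost when any one siWDR82 replicate was left out (-2.84, adjusted p = 0.174 without replicate 2) and with spike-in scaling (-2.28, adjusted p = 0.131). With siZC3H4 its log2 change was -1.95 (adjusted p = 0.369). sequence_13642, at 99.2% spliced reads, had a log2 change of -5.78 with siZC3H4 (SE 0.92, edgeR adjusted p = 0.00516). Its mean gDNA count was only 3.67 in siNT against 73.3 with siZC3H4, while its mean RNA count was 8764 and 4489, so the change lay mostly in gDNA. The siNT gDNA counts were 9, 2 and 0, and the change was -7.80 without siNT replicate 1 and not called without siZC3H4 replicate 1 (adjusted p = 0.0564). The insert met the gDNA minimum only through its siZC3H4 counts of 88, 119 and 13, and was not tested without siZC3H4 replicate 2. With unspliced reads alone neither fall passed, though the log2 changes were -4.33 and -4.45 (adjusted p = 0.353 and 0.727). Of the 10 inserts with the largest fall under siWDR82, 8 had a spliced form listed.

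Inserts with a spliced form listed fell relative to the rest in both knockdowns. The class was unevenly spread over insert numbers, with 80.0% of inserts 12001 to 12500 in it but 8.7% of inserts 1 to 500. As the response also followed insert number (see Other observations) and the class was not compared within number ranges, the tests below do not separate the 2. With siWDR82 their median log2 change was -0.54 against 0.15 for the others, a difference of -0.69 (camera adjusted p = 2.49e-10; adjusted p = 5.13e-05 with an estimated correlation). With siZC3H4 it was -0.39 against 0.14, a difference of -0.52 (camera adjusted p = 2.48e-09; adjusted p = 7.47e-05 with an estimated correlation). With spike-in scaling the class medians were 0.74 and 0.59, below 1.42 and 1.09 for the others, so on that scale the fall was only relative. Insert reads per spike-in read varied between cultures (25.4, 59.5 and 79.5 with siZC3H4), so an absolute fall is neither shown nor excluded. Without the 206 tested inserts that had 0 siNT RNA reads, the medians were -0.55 against 0.13 with siWDR82 and -0.39 against 0.12 with siZC3H4. At matched siNT level the class difference was -0.44 ± 0.027 with siWDR82 and -0.35 ± 0.060 with siZC3H4, where siNT cultures compared with each other had an SD of 0.196 (n = 3). With unspliced reads alone, matched on their own level, it was -0.58 ± 0.030 and -0.51 ± 0.050, with an SD of 0.21 for siNT. Of the 2242 members, 4 rose, 9 fell and 2229 were not called with siWDR82, and 1 rose, 2 fell and 2239 were not called with siZC3H4. Adjusted over the list alone, 0 rose and 0 fell with siWDR82, and 0 rose and 1 fell with siZC3H4. Among the others, 86 rose and 8 fell with siWDR82 (Fisher's exact test, p = 0.000236 for falls and 0.00391 for rises), and 49 rose and 2 fell with siZC3H4 (p = 0.104 for falls and 0.00755 for rises). With the culture as a block, 88 members fell and 13 rose with siWDR82, against 170 and 209 of the others (Fisher's exact test, p = 2.07e-15 for falls). With siZC3H4, 7 fell and 2 rose, against 4 and 48 (Fisher's exact test, p = 0.000268 for falls). The test of falls with siZC3H4 passed only with the block. Fisher's test treats inserts as independent, although all were measured in the same cultures, so these p-values do not measure variation between cultures. Members were 29.2% of the highest of the 5 bins by siNT level but 6.4% of the lowest. The counts of calls were not matched for level, so they do not separate class from level. In each culture the class median minus that of all inserts was 0.86 ± 0.052 in siNT, 0.27 ± 0.048 with siWDR82 and 0.38 ± 0.061 with siZC3H4 (n = 3; exact permutation p = 0.0238 for 6 against 3 cultures). The 141 inserts with 2 or more forms listed had differences of -0.52 and -0.40 (camera adjusted p = 0.000849 and 0.000357; adjusted p = 0.0213 and 0.0149 with an estimated correlation). Without siNT replicate 3 the difference with siWDR82 was -0.34, and per culture the exact permutation p for 6 against 3 was 0.0476, or 0.0667 adjusted.

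Spliced RNA itself made up less of the reads after either knockdown. It was 8.41 ± 0.75% of insert reads in siNT, 4.70 ± 0.44% with siWDR82 and 5.87 ± 0.62% with siZC3H4 (n = 3; exact permutation p = 0.0238 for 6 against 3 cultures, 0.0357 adjusted). Within inserts that have a spliced form listed, the spliced percent was 46.0 ± 2.6, 35.1 ± 1.5 and 38.7 ± 2.3. These inserts gave 18.3 ± 0.66% of insert RNA reads in siNT, 13.4 ± 0.67% with siWDR82 and 15.1 ± 0.71% with siZC3H4, while their share of gDNA reads was 12.3 ± 0.46%, 12.3 ± 0.14% and 12.7 ± 0.43%. Over 1527 inserts with enough reads of both forms, the median log2 of spliced over unspliced reads was -0.0049 ± 0.023, -0.41 ± 0.045 and -0.13 ± 0.065. The median of the changes fitted by edgeR was -0.36 with siWDR82, with 60.6% of these inserts below 0, but only -0.065 with siZC3H4, with 52.9% below 0. Per insert, the edgeR test of that ratio called 2 up and 0 down with siWDR82 and 3 up and 0 down with siZC3H4, with 113 and 70 inserts at an unadjusted p under 0.05. The same test recovered 0% of simulated 4-fold changes in the siWDR82 comparison.

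**Figure D2:**
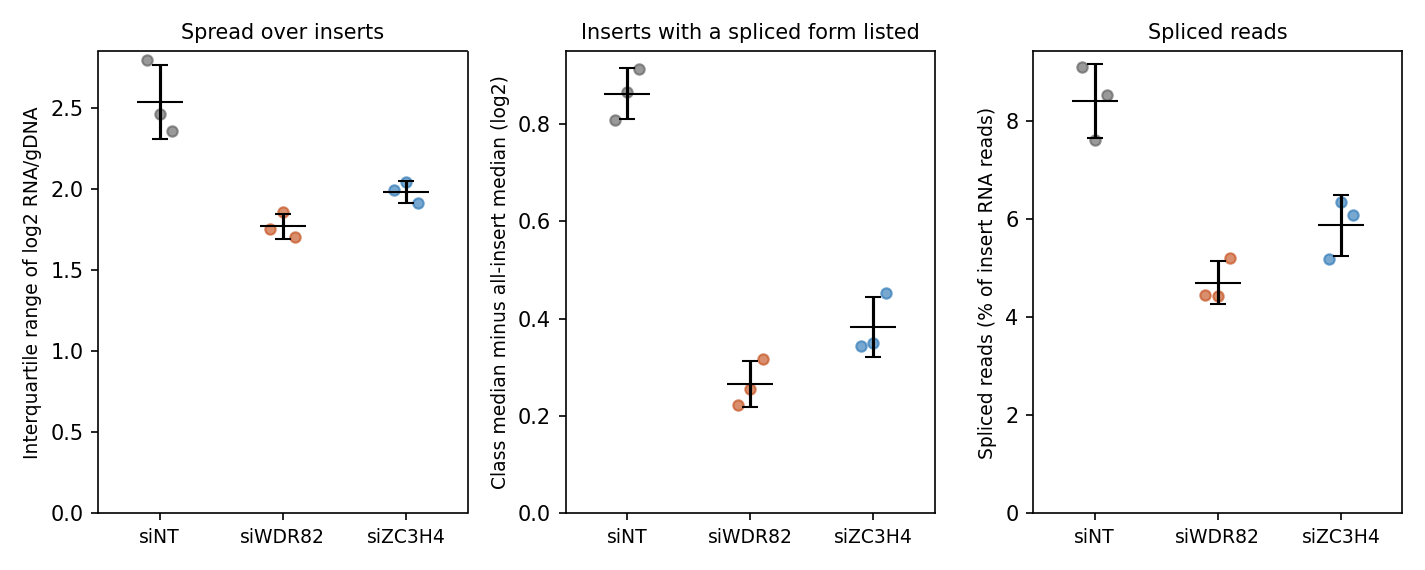
Each point is a culture, and bars give the mean and SD of 3 cultures per siRNA, for the interquartile range over inserts of log2 RNA over gDNA (left), the median log2 RNA over gDNA of inserts with a spliced form listed minus that of all inserts (middle) and the spliced percent of insert RNA reads (right). All 6 knockdown cultures lie below all 3 siNT cultures in each panel.

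Calls of both siRNAs overlapped. Rises called with both numbered 48 and falls 1. In 20 simulations with no effect and one siNT group for both nothing was called, and lists of the same lengths by lowest p, 107 and 54, shared 8.55 inserts on average and at most 11. Of 112 inserts called in either comparison, 112 had the same sign in both, but sharing siNT alone gave 101 to 111 of the 112 inserts with the lowest p in those simulations. Across inserts, which are not independent replicates, the changes correlated with r = 0.77, against 0.50 in simulations with no effect and one siNT group for both. The covariance was 1.06 against a simulated 0.57, a difference of 0.49. The 3 siNT cultures are too few to split, so part of the excess overlap may come from the shared controls.

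Tested directly, siZC3H4 and siWDR82 differed for 0 inserts (edgeR), with 292 at an unadjusted p under 0.05 where 768 would be expected by chance. DESeq2 called 32, limma called 0, and edgeR on the libraries of those siRNAs alone called 1. The class with a spliced form listed differed by 0.088 between them (camera adjusted p = 0.297). The spliced-over-unspliced median was 0.28 higher with siZC3H4 than with siWDR82, and the lowest-minus-highest difference was -0.31 (exact permutation p = 0.1 each, n = 3, the smallest possible). Neither result shows that the siRNAs act alike or apart.

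gDNA representation gave the background. For gDNA alone, edgeR called 0 inserts with siWDR82 and 0 with siZC3H4, with 590 and 926 at an unadjusted p under 0.05. DESeq2 called 32 over both comparisons, and edgeR without siNT replicate 1 called 129. RNA libraries alone, without gDNA, called 197 up and 433 down with siWDR82 and 2 up and 5 down with siZC3H4.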

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

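The tests of RNA without gDNA were chosen after the result was seen. Inserts without any gDNA read lie outside the comparisons, yet RNA libraries held 106965 reads assigned to them, 0.028% of insert reads. Of 244 such inserts, 38 had over 3 RNA reads in a library. The reads were 97.7% spliced, and 2 inserts held 76.2% of them. Of the 38, 16 had no form listed and 1761 reads. Inserts present in the pool but below detection in gDNA stay open: 20 of the 22 with a form listed were over 50% spliced, but so were 98.2% of the 113 tested inserts with a form listed and the highest RNA over gDNA. A spliced form was listed for 22 of the 38 but for 7 of the other 206 (Fisher's exact test, p = 1.87e-15), as would follow if spliced sequences are shared between inserts. That hypothesis may also bear on single inserts with mostly spliced reads. The split is itself by RNA reads and was made after the 97.7% was seen, so it does not favour shared sequences over inserts below detection. No biological explanation was tested.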

How the results depend on the processing

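Alternatives with unspliced reads alone, the culture block and spike-in scaling for the class, single spike-ins, a minimum mean count of 100, inserts of at most 3 siNT reads left out, and the checks on spread, level bins, spliced share and reads per spike-in read were chosen after seeing the data. The class difference kept its direction and its camera call in 17 of 17 alternatives with siWDR82 and 17 of 17 with siZC3H4; fry, which tests the class against no change, passed too. The interquartile range and the difference between lowest and highest bin moved by less than the siNT SD, the larger one, in 9 of 9 alternatives for each siRNA. Counts of single inserts depended on the setting, and the cause was not tested except where fewer inserts or libraries entered. For siWDR82 against 107 calls, DESeq2 gave 473, limma 0, RNA libraries alone 630, the culture as a replicate block 480, spike-in scaling 614, the libraries of the compared siRNAs alone 42, and leaving out inserts of at most 3 siNT RNA reads 27. For siZC3H4 against 54 calls, library totals gave 90, DESeq2 264, limma 2, RNA alone 7, spike-in scaling 89, the compared siRNAs alone 23, and leaving out inserts of at most 3 siNT RNA reads 10. Between the siRNAs, DESeq2 gave 32 and their libraries alone 1, against 0. Leaving out one replicate at a time gave 20 to 251 calls for siWDR82, 12 to 246 for siZC3H4, a correlation of both changes of 0.73 to 0.87 against 0.79 fitted, and 0 to 129 gDNA calls. DESeq2 gave 32 gDNA calls. The replicate number as a block gave 32 calls for siZC3H4; same-numbered cultures of different siRNAs correlated by -0.0085 to 0.14, over 0.1 in 2 of 9 pairs, so numbers do not pair them. The culture block changed no camera call of the class. With a pseudocount of 2 CPM the siNT range was 26.4-fold and the class difference in siNT level 0.94; a stricter filter gave 0.93, and unspliced reads alone turned it to -0.19. A minimum mean count of 100 gave -0.45 for the spliced-over-unspliced change with siWDR82. Alternatives planned for sequence features, matched variants and gene lists were not run.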

Other observations

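Among these tests, those of shared spread, exchanged reads, carried-over DNA, both siRNAs together, unspliced reads, matched level, amplification slope and number blocks were chosen after the results were seen; those of number blocks with level removed and other splits were not.

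The response followed the insert number, which the tables leave without meaning. In 33 blocks of 500 consecutive numbers, inserts 1 to 500 had a median siNT level of 0.11 and a median log2 change of -0.20 with siWDR82, whereas inserts 9001 to 9500 had -1.95 and 0.50. Inserts 12001 to 12500, of which 80.0% had a spliced form listed, had 0.63 and -0.76 with siWDR82 and -0.46 with siZC3H4. Blocks held at least 6.97% of the variance of the log2 change in either knockdown, against at most 0.453% in 1000 random orders. After siNT level and the spliced class were regressed out, the lower share was 3.10%, against at most 0.474%, so these features as measured did not account for the blocks, and what the blocks share may be a feature of sequence that was not analysed here.

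For the narrower spread in both knockdowns, more independent noise between siNT cultures is argued against as the whole cause. The SD shared between cultures was 1.65 in siNT and 0.32 lower in the nearer knockdown, with at most 0.035 between pairs. That value cannot decide on noise that lowers the same inserts in every siNT culture, since it would widen the shared SD too. RNA replicates did differ more in siNT. The lowest chi-square per degree of freedom was 421 in siNT, 273 with siWDR82 and 247 with siZC3H4. Carried-over DNA would compress the differences that cultures share: with gDNA mixed by calculation into the siNT libraries until the lowest level bin rose as observed, the shared SD there fell from 1.05 to a mean of 0.56 for the nearer knockdown. In the knockdowns it was 0.99 and 1.06, above the prediction by at least 0.422 (SD over rankings at most 0.063), which argues against it as the whole cause. Reads exchanged between inserts stay open, because the tables do not give their profile; with an assumed equal amount per insert the observed shared SD was at least 0.338 above the prediction. Loss of the complex targeted by both siRNAs remains a hypothesis. The permutation p of 0.0238 for 6 against 3 cultures describes the pattern itself, so it does not test that cause.

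For the relative fall of inserts with a spliced form listed, misassigned spliced reads are argued against, since with unspliced reads alone the difference was -0.56 with siWDR82 and -0.44 with siZC3H4. Amplification that favours short spliced products where insert RNA is scarce was tested on the spliced percent of insert reads and not on the class difference. For that percent it is argued against by a slope within groups of 0.199 percent per log2 unit (95% interval -0.93 to 1.33), where the fall of the percent needs -3.91. Carried-over DNA would act alike on inserts of equal unspliced level. It is argued against as the whole cause of the class fall, since unspliced reads at matched level gave -0.51 in the nearer knockdown. That was over 2 SD of siNT cultures compared with each other (SD 0.21, n = 3). The match does not test the general trend with the siNT level of all reads. Class members differed from the others by 1.08 in that level but by -0.19 in unspliced level, so at equal unspliced level they had more RNA. The matched difference with all reads was -0.44 with siWDR82 and -0.35 with siZC3H4 (siNT SD 0.196), which left the trend undecided for siZC3H4. The unspliced match was added after that result. For the lower spliced percent carried-over DNA is argued against likewise as the whole cause. With gDNA mixed in at ratios of 0.44 for siWDR82 and 0.31 for siZC3H4, the shared SD of the lowest level bin was 0.32 and 0.38. That was at least 0.633 below the shared SD observed. The fall of the percent would need higher ratios, and the smaller ratios that matched the rise of that bin had given a larger shared SD.

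For the counts of called inserts, the 10 splits of 6 cultures into 3 and 3 are too few for a share under 0.05. Fitted on the cultures of the siRNAs compared, siWDR82 against siNT gave 42 calls and the highest other split 2, so 1 of 10 splits gave as many, and siZC3H4 against siNT gave 23 and the highest other split 1, again 1 of 10. siWDR82 against siZC3H4 gave 1 call and the highest other split 1, as many in 2 of 10.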
